A study of Mytilus edulis with 23 samples.

How the data were processed

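RNA of blue mussels (Mytilus edulis) was measured on 23 custom 2-colour Agilent arrays designed, per the labels, on a transcriptome assembled de novo. Total RNA was extracted with Trizol and labelled with the Low Input Quick Amp kit, per the labels' protocols, with each sample in Cy5 and a reference pooled from all stages in Cy3. The same dye orientation was used on each array, so a dye effect is shared by all samples and does not average out within a group. Groups were taken from the sample labels, which give the stage, the diet and a replicate number, and each replicate is 1 independent culture of 1 larval family produced from pooled gametes.

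The scanner files hold the intensity of each spot and of its local background in both channels, on a linear scale without normalization, made with Agilent Feature Extraction 10.7.3.1 per the file headers. They also hold processed intensity values, which that program had background-subtracted and dye-normalized, and the log10 ratio of Cy5 over Cy3 made from them, per the file headers. The deposited series matrix holds log10 ratios. Its values differed from the scanner files' log10 ratios by at most 0.005, so its scale, centring and direction are those of the scanner program, and its column medians ranged from -0.0987 to 0. A second deposited table holds ratios normalized by the authors by quantiles, taken here as log2 ratios from their range and from limma, which the submitters' processing notes name without a version. Its base, background correction and order of steps are not given in the sources used here, and its column medians ranged from -0.12 to 0.0429. Both tables were used as alternatives, and 0 columns of per-sample values were left unused.

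Each array has 62976 spots. After the 1319 control spots and 1400 spots of a titration series were set aside, 60257 spots of 58600 probes remained, of which 857 probes were printed more than once. The median spot and background signals were used, since the scanner files hold no mean spot signal, although the design written beforehand named it. Background was corrected with normexp (offset 50) and log ratios were normalized within each array by loess, with control spots at weight 0. Spots marked as outliers were set to missing, saturated spots were kept, and spots of a probe were averaged. A probe was tested when its Cy5 signal was well above background on all arrays of at least 1 of the 8 groups, which held for 39403 probes. R 4.3.3, limma 3.58.1, statmod 1.5.0 and the data.table package, version 1.17.8, were used, and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

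The files name 30856 of the 58600 probes, 25850 of them among those tested, and each name is only the first word of a description, with 4876 distinct names. A name such as ribosomal, fatty or g-type therefore stands for a probe whose full description was not used here, and what a name is known to do is given only where 1 word identifies it. No chromosome position or exon could be given for the probes, since the reference tables carry no probe identifiers. Consecutive probes mostly form pairs that target 1 transcript. Of 15378 such pairs 99.21% had the same name, the median correlation of their log2 Cy3 signal within an array was 0.907, and log2 changes of the 12172 tested pairs correlated at 0.864 to 0.925 across pairs, which are not independent replicates. Counts of probes called over all probes are therefore given with counts of transcripts for the comparisons, the lists and the within-slide values, while counts over a list alone and under other settings are of probes only. Beside a named probe the value of the other probe of its transcript is given where the 2 log2 changes differ in sign or by over 2 times, unless either was not well above background on any array of a group, or where only 1 of them was called over the stages.

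A limma model with 1 mean per group was fitted to log2(Cy5/Cy3) of all 23 arrays, which share 1 estimate of the spread, and tested with empirical Bayes moderation. A moderated F-test covered the 5 groups without the Tiso diet. The adjacent stages within each diet, the diets at each of 3 stages, the mean of the 3 diet differences and their differences between stages were tested likewise. All tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. Standard errors (SE) come from the moderated fit and standard deviations (SD) from the arrays. The number of arrays limits the precision: the median SE of a log2 change was 0.276 for 3 against 3 arrays, 0.309 for comparisons with the 2 Tiso juveniles and 0.166 for the mean over stages. A probe not well above background on any array of a group has only a bound there, given as at least N-fold. It sets the bright group's mean against the dim group's mean of, per array, the higher of the floor and the probe's own signal, in the Cy5 channel after loess and Aquantile, and dyes were not swapped. A dye effect of a probe that is the same on all arrays cancels where the probe's own signal is used on both sides, but not where the floor, set by another probe, takes its place, and one that varies between arrays was not tested.

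The groups, the tests, the alternatives, 21 gene lists and the rule for named genes were fixed before the data were examined. Because names turned out to be single words, 20 of the lists were rewritten for such words, fatty acid synthesis and oxidation becoming 1 list, after the names and before any test result were seen, and the lists as first written were run as an alternative. The lists covered fatty acid metabolism, lipid transport and storage, lipid mediator enzymes, shell formation, foot and byssus, muscle, cilia, digestive enzymes, immune effectors, chaperones, antioxidant enzymes, ribosomal proteins, cell cycle, oxidative phosphorylation, neural genes, developmental factors, apoptosis, proteasome, egg envelope and germ line, and algal names. Lists were tested with camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over the 20 lists per comparison, and their members in the F-tests with Fisher's exact test. With the estimated correlation 0 of the 20 lists were called in each of the 10 comparisons, so no list's call held in both versions, with or without the slide as a block.

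Named genes were chosen by a fixed rule. Per comparison these were the 10 largest rises and 10 largest falls among named probes past the threshold whose replicates did not overlap, with 1 probe per name, and in each list up to 4 members with the smallest p, of which the text gives a part. For the mean over stages the probe had to have the same sign at each stage, and for the differences between stages non-overlap was dropped.

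Alternatives were the scanner program's processed signals followed by loess, median centring, Aquantile scaling, the Cy5 channel alone, both deposited tables, no and a stricter probe filter, 1 probe per name, fits on the compared groups alone, array weights, a prior with trend and robust estimation, a 2-fold minimum, the replicate number as a block, the slide as a block, and leaving out each array in turn. After the data were seen 6 more were added: leaving out the array with almost no signal, leaving out the 4 arrays with under 25% of spots well above background in Cy5, the mean of the probes of a transcript, the lists as first written, the slide as a block with an estimated correlation for the lists, and differences within each slide. The method was tested on values simulated for 39340 probes, 200 of them changed. The values were independent normal noise with each probe's own spread. No shift shared by the probes of an array or slide was simulated, so recovery and false calls can differ on the real arrays. For trochophores against eggs the method recovered 20% of probes changed by 1 log2 unit and 78% of those changed by 2, with 5 false calls. The shares were 34% and 81% for Tiso pediveligers against Tiso veligers (4 false calls), 37% and 82% for the diets in veligers, 16% and 72% in juveniles, and 62% and 92% for the mean over stages. The stage F-test recovered 68.5% of probes changed by 2 log2 units, and the test of differences between stages 43%. In simulated arrays with shifts shared within an array and no group effect, camera called 15 of 20 lists at its preset correlation and 0 with an estimated one, in the design of trochophores against eggs. Each list had its own random shift per array, of 1 size for all lists. That size was larger than the spread of most real list medians among eggs, whose SD ran from 0.026 (fatty acid metabolism) to 0.703 (foot and byssus). The 15 calls therefore do not estimate how often camera calls falsely on the real arrays.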

Results

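Gene expression was followed over 5 stages of blue mussel development, on 2 diets from the veliger onwards. Eggs (0 days post fertilization) and trochophores (1 day), the first swimming larvae, received no diet treatment. Veligers (15 days), pediveligers (22 days), which carry a foot and are near settlement, and juveniles (42 days) came from cultures fed either a cocktail of 3 microalgae, abbreviated COC, or the Tiso diet, whose label names Nannochloropsis oculata alone. The series title describes the study as a control against a diet deficient in fatty acids. Each group had 3 arrays, 1 per culture, except the Tiso juveniles with 2, and all cultures held 1 larval family. The p-values therefore measure the spread between arrays of that family. That spread holds differences in slide and signal as well as those between cultures.

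Signal differed widely between arrays. The share of spots well above background in Cy5, the sample channel, was 11.8%, 34.0% and 18.6% in the 3 eggs and 21.2%, 63.7% and 74.4% in the 3 trochophores. It ranged from 33.7% to 71.6% in COC veligers, 47.2% to 74.9% in COC pediveligers, 67.6% to 73.9% in COC juveniles, 60.3% to 67.7% in Tiso veligers and 40.8% to 63.3% in Tiso pediveligers. Tiso juvenile 2 had 58.6%, whereas Tiso juvenile 1 had 0.088% in Cy5 and 0.674% in Cy3, so its ratios carry almost no signal. The arrays lay on 3 slides. Slide 1 held the eggs, the trochophores and COC veligers 1 and 2. Slide 2 held COC veliger 3, the COC pediveligers, the Tiso veligers and Tiso pediveliger 1, and slide 3 held the remaining arrays.

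Replicates of a group were often less alike than arrays of other groups. Over the 22 arrays with signal, Pearson's r of log2 ratios across the tested probes averaged 0.294 over 21 pairs of the same label and 0.0937 over 210 pairs of different labels. Pairs of different labels averaged 0.291 on the same slide (54 pairs) and 0.0255 on different slides (156 pairs). The closest array carried another label for 14 of the 22 arrays and lay on the same slide for 18. The 3 arrays labelled trochophore did not correlate with one another (r from -0.085 to 0.042), and each was close to an array of another group: array 1 to egg 3 (0.834), array 2 to COC pediveliger 2 (0.574) and array 3 to Tiso veliger 2 (0.824, on another slide). COC veliger 3 correlated with COC pediveliger 2 at 0.817 and COC juvenile 3 with Tiso pediveliger 3 at 0.86. Of 253 pairs 5 had r below -0.3 (3 over all probes), the lowest -0.355; the dyes are stated in the labels, so directions were kept. The highest r between any 2 arrays was 0.862 (Tiso pediveligers 2 and 3), so each was counted as a separate array.

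**Figure D1:**
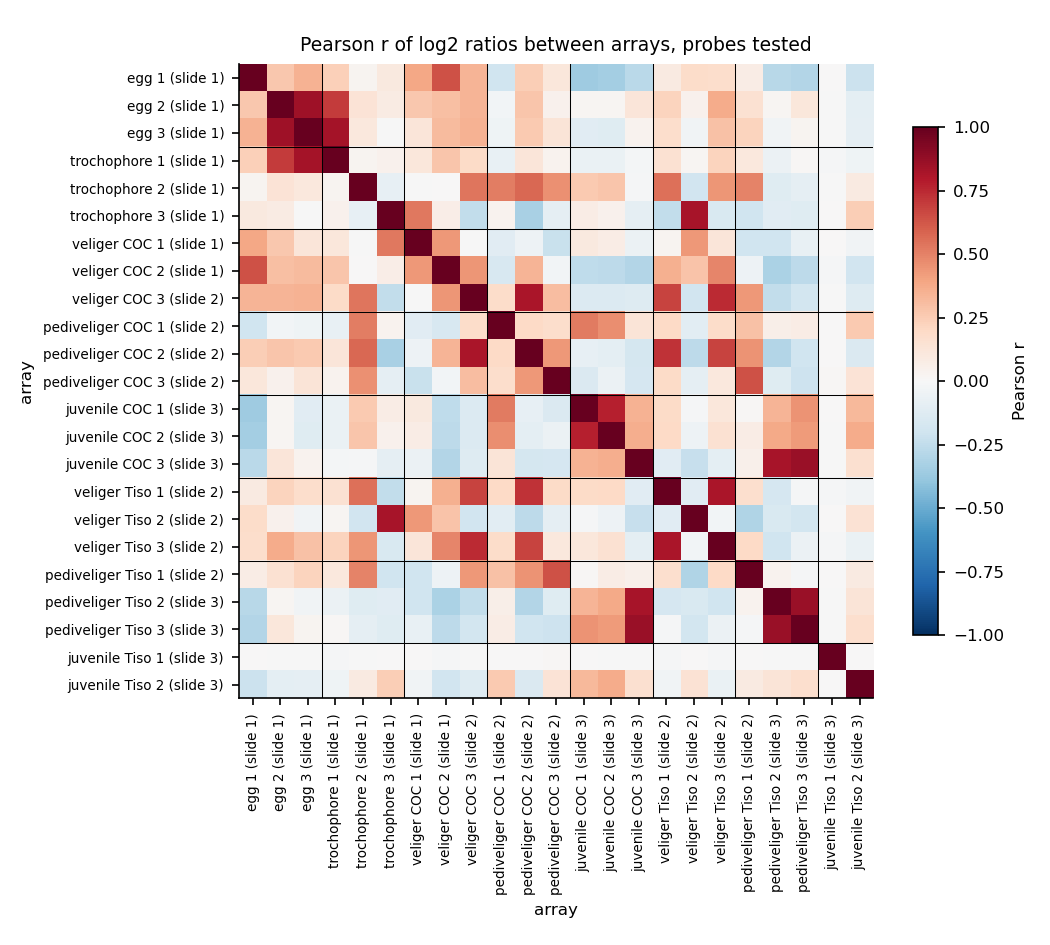
Pearson r (colour scale from -1 to 1) of log2 ratios over the probes tested, between all 23 arrays, with group and slide named on both axes and lines between groups. Egg 3 and trochophore 1 (0.834) and trochophore 3 and Tiso veliger 2 (0.824) are pairs of different labels, and Tiso juvenile 1 is near 0 with each other array.

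Across eggs, trochophores and the COC-fed stages, ribosomal protein genes, which build the ribosome, had the most changed members of the lists. Of 324 probes of 170 transcripts 34 of 21 transcripts changed (97 probes when adjusted over the list alone). Fisher's exact test gave an adjusted p of 2.38e-34, but it treats probes as independent, although many share a transcript and all share the arrays, and with the slide as a block 0 of the 34 were called. The mean log2 ratio of these 34 to the reference was -1.36 ± 0.19 in eggs (SD, n = 3), -0.05 ± 0.12 in trochophores, -0.75 ± 0.33 in veligers, -0.12 ± 0.23 in pediveligers and 0.38 ± 0.18 in juveniles. Of the 34, 33 were lowest in eggs and 33 highest in juveniles. The median of all 324 took another course, with -0.26 ± 0.06 in eggs, -0.02 ± 0.20 in trochophores, -0.33 ± 0.28 in veligers, 0.14 ± 0.16 in pediveligers and 0.005 ± 0.12 in juveniles. One ribosomal probe (CUST_14210_PI427809864) went from -1.67 ± 0.18 in eggs to 0.44 ± 0.11 in juveniles (adjusted p = 0.000606). One named 40s, for the small ribosomal subunit, went from -1.87 ± 0.12 to 0.32 ± 0.21 (adjusted p = 0.016), but the other probe of its transcript was at 0.66 in eggs and -1.11 in juveniles (adjusted p = 0.303). Of digestive enzymes 10 of 159 probes changed, of 6 of 81 transcripts (adjusted p = 4.75e-08 in the same test; 52 adjusted over the list alone; 0 with the slide as a block), and the median of the list was lowest in veligers, at -1.24 ± 0.54 against -0.78 ± 0.42 in eggs. A probe for cathepsin, a lysosomal protease, was at -3.54 ± 1.15 in eggs, -2.69 ± 0.59 in veligers and 0.23 ± 0.40 in juveniles (adjusted p = 0.0201). One named beta-glucan was at -3.48 ± 1.16, -3.01 ± 0.38 and 0.44 ± 0.32 (adjusted p = 0.0179). That word put it in this list, here and below, but does not show that it is an enzyme.

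Other lists had few changed members. A probe named fatty, the first word of fatty acid proteins, lay at -3.46 ± 1.13 in eggs and 0.83 ± 0.34 in juveniles (adjusted p = 0.0164). It was 1 of 2 probes of 1 transcript that changed among 166 probes of 88 transcripts of fatty acid metabolism (Fisher's exact test, adjusted p = 0.63). Among immune effectors 6 of 567 changed, of 4 of 296 transcripts (adjusted p = 0.347; 23 adjusted over the list alone). One named g-type was lowest in veligers (-3.23 ± 0.89) and highest in juveniles (0.23 ± 0.61; adjusted p = 0.0304). A probe named dynein, a motor protein name of the cilia list, went the other way, from 0.84 ± 0.06 in eggs to -0.25 ± 0.03 in juveniles (adjusted p = 0.0289, and adjusted p = 0.309 for the other probe of its transcript). Of 215 cilia probes 2 changed, of 2 transcripts (adjusted p = 0.766). A probe named dopamine lay at -4.16 ± 1.09 in veligers and 0.07 ± 0.94 in juveniles (adjusted p = 0.0338), and 2 of 169 neural probes changed, both of 1 transcript (adjusted p = 0.63). Of muscle 0 of 137 changed, against 31 adjusted over the list alone, and of shell formation 1 of 132, against 14.

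In all, limma's F-test called 185 probes of 136 transcripts, 105 of them named. Juveniles had the highest mean for 143 of the 185, and eggs the lowest for 98 and veligers for 57. With the slide as a block 0 probes were called, and no slide held all 5 groups. Other scalings gave larger counts, which stand in the part on processing. The count depended on single arrays: without egg 1, 2 or 3 it was 5055, 2 or 1, without trochophore 1, 2 or 3 it was 507, 108 or 37, without COC veliger 1, 2 or 3 it was 1567, 26 or 768, without pediveliger 2 or 3 it was 341 or 67, and without juvenile 1, 2 or 3 it was 1, 1 or 18.

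**Figure D2:**
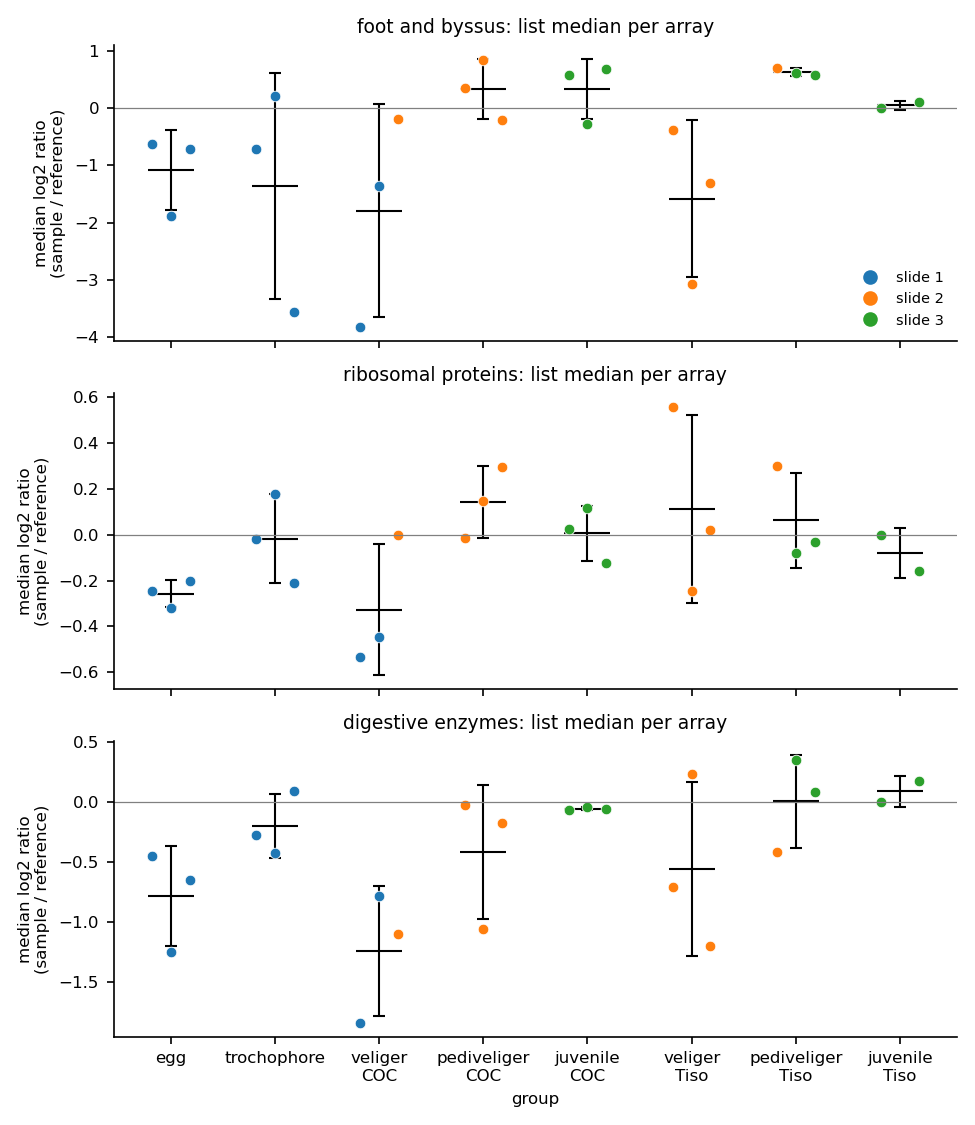
Median log2 ratio of sample over reference of the members of 3 gene lists on each array (points, coloured by slide), by group, with the group mean and SD (lines; n = 3 arrays, 2 for Tiso juveniles). The 3 Tiso pediveligers have foot and byssus medians from 0.58 to 0.70, whereas the 3 Tiso veligers range from -3.07 to -0.38.

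From egg to trochophore 1 ribosomal probe rose, from -1.67 ± 0.18 to -0.15 ± 0.20 (SD, n = 3 each), a log2 change of 1.52 ± 0.18 (SE; adjusted p = 0.00523; trochophores above eggs on 3 of 3 arrays). The other probe of its transcript had 1.28. Other ribosomal probes had 1.84 ± 0.29 and 1.62 ± 0.26, neither past the threshold (adjusted p = 0.0738 for both). The other probe of the latter's transcript was not well above background on any egg array. The 324 ribosomal probes had a median change of 0.19 (227 positive; 70 higher adjusted over the list alone; camera's adjusted p = 1.13e-12, and adjusted p = 0.551 with an estimated correlation). Digestive enzymes had a median of 0.53, with 29 higher and 3 lower adjusted over the list alone (adjusted p = 4.08e-14, and adjusted p = 0.551 with an estimated correlation). Among them were cathepsin at 3.24 ± 0.59 (adjusted p = 0.0738) and beta-glucan at 3.03 ± 0.60 (adjusted p = 0.104). Cell cycle genes had a median of -0.48 (94 of 114 negative; adjusted p = 2.19e-09, and adjusted p = 0.551 with an estimated correlation). Cyclin, which drives cell division, was at -1.22 ± 0.37 (the other probe of its transcript -0.17) and wee1-like, a kinase that holds back mitosis, at -1.51 ± 0.43. The cell cycle median was -0.75 without egg 1 and -0.20 without egg 2, the 3 eggs having list medians of -0.056, 1.17 and 0.64 and the 3 trochophores 0.27, -0.052 and -0.014. The ribosomal median was -0.006 without trochophore 2 and 0.58 without trochophore 3, and that of digestive enzymes 0.34 without trochophore 3.

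Immune effectors had a median change of 0.23 (adjusted p = 3.84e-06, and adjusted p = 0.743 with an estimated correlation), with g-type at 3.09 ± 0.72 and c-type at 2.86 ± 0.65. Neural genes had 0.22 (adjusted p = 9.22e-05, and adjusted p = 0.551 with an estimated correlation) and developmental factors 0.13 (adjusted p = 0.0271, and adjusted p = 0.713 with an estimated correlation). Odd, a developmental regulator, was at 3.40 ± 0.60 and neuroendocrine at 2.57 ± 0.63. Without egg 2 the medians of these 3 lists were 0.13, 0.056 and 0.028, which ended the call for the last 2 (adjusted p = 0.0986 and 0.465). Without trochophore 2 they were 0.36, 0.13 and 0.054 (the last not called, adjusted p = 0.149), without trochophore 3 immune effectors had 0.15, and without egg 1 developmental factors had 0.19. Egg envelope and germ line genes had -0.19 and were not called (adjusted p = 0.319), with 0.30 under median centring and 0.074 in the series matrix, which moved the median of all probes by 0.33 and 0.42. The median was -0.10 without egg 1, -0.093 without egg 2 and -0.089 without trochophore 3, and was not called in any of these. A probe named fatty had 3.13 ± 0.54, and the shell matrix probe BMSP -2.31 ± 0.52 (the other probe -0.79). The cyp-like (-3.95 ± 1.23) and nadh (-4.09 ± 1.30) probes had large values and large errors, and both turned positive in the Cy5 channel alone (0.16 and 0.066). In limma 1 probe was called, higher in trochophores, with 4428 at an unadjusted p under 0.05. All 6 arrays lay on slide 1, so the within-slide medians equal those given and 1 probe was called with the slide as a block. The call ended without egg 3, trochophore 2 or trochophore 3 (0 called for each). The count was 3524 without egg 1 and 22 without trochophore 1, and the Cy5 channel alone called 48 higher and 48 lower.

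From trochophore to COC veliger, digestive enzymes had the largest list shift, with a median log2 change of -1.24 and 134 of 159 probes negative (43 lower adjusted over the list alone; camera's adjusted p = 1.25e-26, and adjusted p = 0.281 with an estimated correlation). Cathepsin was at -3.38 ± 0.78 (SE, n = 3 and 3), beta-glucan at -2.56 ± 0.60 and chymotrypsinogen, the precursor of an intestinal protease, at -2.52 ± 0.60, none past the threshold (limma adjusted p = 0.392 for each). Ribosomal proteins had a median of -0.35 (adjusted p = 1.42e-15, and adjusted p = 0.281 with an estimated correlation), with 1 probe at -0.79 ± 0.19. Immune effectors had -0.41 (adjusted p = 3.35e-15, and adjusted p = 0.424 with an estimated correlation), with g-type at -2.84 ± 0.65. The proteasome, which degrades tagged proteins, had -0.27 (adjusted p = 1.3e-07, and adjusted p = 0.424 with an estimated correlation), with 1 probe at -1.13 ± 0.32. Oxidative phosphorylation had -0.28 (adjusted p = 0.000236, and adjusted p = 0.534 with an estimated correlation), a direction that turned with the slide as a block (0.044, adjusted p = 0.78) and without COC veliger 3 (0.044, adjusted p = 0.846). The 13 probes with algal names had -0.60 (adjusted p = 0.0143, and adjusted p = 0.424 with an estimated correlation). Further values were -1.99 ± 0.50 for perlucin, a shell nacre protein, -2.98 ± 0.77 for dopamine, -2.52 ± 0.59 for odd and -3.05 ± 0.81 for phospholipase.

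Over all probes limma called 0, with 3302 at an unadjusted p under 0.05 and a smallest adjusted p of 0.29. Within slide 1 (2 veligers, 3 trochophores), which is also the value with the slide as a block, 101 probes of 83 transcripts were called, 61 higher and 40 lower in veligers. There the medians were -1.22 for digestive enzymes, -0.64 for ribosomal proteins, -0.38 for immune effectors, -0.21 for the proteasome and -0.98 for algal names. Without COC veliger 1 the count was 979, and without COC veliger 3 it was 117. Without COC veliger 1 the list medians were -0.76 for digestive enzymes, -0.21 for ribosomal proteins, -0.25 for immune effectors, -0.49 for oxidative phosphorylation and -0.11 for algal names (the last not called, adjusted p = 0.54). Algal names had -0.98 without COC veliger 3, and -0.26 without trochophore 1, which ended the call (adjusted p = 0.145). Ribosomal proteins had -0.64 without COC veliger 3, -0.18 without trochophore 2 and -0.65 without trochophore 3. The proteasome had -0.41 without trochophore 2. Oxidative phosphorylation had -0.58 without trochophore 2, -0.52 without COC veliger 2, and -0.17 without trochophore 3, which ended its call (adjusted p = 0.0554).

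From COC veliger to COC pediveliger, genes of the foot and byssus, the threads that hold mussels to rock, had the largest median log2 change of the lists. It was 2.33, with 24 of 26 probes positive (12 higher adjusted over the list alone; camera's adjusted p = 7.13e-11, and adjusted p = 0.308 with an estimated correlation). Foot was at 3.06 ± 1.15 (SE, n = 3 and 3), precollagen, a byssal collagen, at 2.46 ± 0.82 and the proximal thread protein at 2.46 ± 0.84, none past the threshold (adjusted p = 0.409, 0.39 and 0.393). Ribosomal proteins had 0.64 (298 of 324 positive; adjusted p = 2.2e-27, and adjusted p = 0.14 with an estimated correlation), with 1 probe at 0.79 ± 0.20. The fry test, which takes the list by itself, gave an adjusted p of 0.0305. This was the only list that fry called, with 0 called in each other comparison. Digestive enzymes had 0.81, with 25 higher and 1 lower adjusted over the list alone (adjusted p = 2.58e-14, and adjusted p = 0.308 with an estimated correlation). Among them endoglucanase, which digests cellulose, was at 3.26 ± 0.68, beta-glucan at 2.72 ± 0.60 and carboxypeptidase at 3.21 ± 0.80. Immune effectors had 0.43 (adjusted p = 2.6e-11, and adjusted p = 0.431 with an estimated correlation), with g-type at 3.07 ± 0.64. Further values were 1.78 ± 0.43 for perlucin, 1.25 ± 0.30 for the dynein light chain tctex1, -3.01 ± 0.83 for the shell protein prism and -0.94 ± 0.22 for origin.

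Over all probes 0 were called by limma, with 4106 at an unadjusted p under 0.05 and a smallest adjusted p of 0.292. Within slide 2 (3 pediveligers, 1 veliger, as with the slide as a block) 0 were called (987 unadjusted). The medians there were 0.45 for foot and byssus (adjusted p = 0.299), 0.41 for ribosomal proteins, 0.74 for digestive enzymes and 0.40 for immune effectors. The foot and byssus list was at -3.83, -1.36 and -0.19 on the 3 veliger arrays. The count was 881 without veliger 3, 20 without pediveliger 1 and 19 without pediveliger 2. Without veliger 1 the medians were 1.26 for foot and byssus and 0.25 for immune effectors, and without pediveliger 2 that of digestive enzymes was 1.26.

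From COC pediveliger to COC juvenile, across metamorphosis, cilia genes, which serve larval swimming, had a median log2 change of -0.25 (142 of 215 negative; camera's adjusted p = 5.63e-07, and adjusted p = 0.643 with an estimated correlation). Dynein was at -0.98 ± 0.24 (SE, n = 3 and 3) and axonemal at -1.58 ± 0.39 (the other probe of its transcript -0.61). Muscle genes had -0.36 (102 of 137 negative; adjusted p = 6.2e-06, and adjusted p = 0.643 with an estimated correlation), with tropomyosin at -0.72 ± 0.21 and titin, the giant spring protein of muscle, at -0.95 ± 0.26 (the other probe -0.46). Immune effectors had 0.37 (509 of 567 positive; adjusted p = 4.2e-09, and adjusted p = 0.643 with an estimated correlation), with c1q, a family of recognition proteins, at 1.19 ± 0.36 (the other probe 0.59). Ribosomal proteins parted, with 22 higher and 93 lower adjusted over the list alone and a median of -0.23 (adjusted p = 0.000473, and adjusted p = 0.643 with an estimated correlation). One ribosomal probe was at 0.72 ± 0.18 and one named 60s, for the large subunit, at -1.97 ± 0.54. Further values were -0.92 ± 0.19 for goosecoid, a homeobox factor, 0.83 ± 0.23 for prefoldin, a chaperone, and 0.55 ± 0.20 for carbonic, none of these probes past the threshold (limma adjusted p = 0.432 for each).

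By limma 0 probes were called, with 4196 at an unadjusted p under 0.05. The groups share no slide, so no within-slide value exists. The slide block rests here on Tiso pediveliger 1 against Tiso pediveligers 2 and 3 alone, with which it correlated at 0.036 and -0.015. With the slide as a block 0 were called and the medians were 0.19 for cilia (adjusted p = 0.000169, and adjusted p = 0.738 with an estimated correlation) and -0.26 for immune effectors (adjusted p = 7.99e-05, and adjusted p = 0.738 with an estimated correlation), both reversed, -0.046 for muscle and -0.12 for ribosomal proteins. Median centring, which moved the median of all probes by 0.45, gave positive medians for cilia (0.46), muscle (0.56) and ribosomal proteins (0.65). Without pediveliger 1 the count was 22, and without pediveliger 2 the immune median was 0.19.

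Between Tiso veligers and Tiso pediveligers 71 probes rose and 16 fell. Of 567 immune effectors 4 rose, of 3 transcripts, among them c1q by 4.47 ± 0.83 log2 units (SE, n = 3 and 3; limma adjusted p = 0.0406) and apextrin-like by 2.41 ± 0.47 (adjusted p = 0.0449). Another apextrin-like probe was at least 4.06-fold higher (adjusted p = 0.0415). Of 132 shell formation probes 3 rose, of 2 transcripts, perlucin by 2.33 ± 0.39 (adjusted p = 0.0192) and 2.46 ± 0.46 (adjusted p = 0.0406) on the 2 probes of a transcript, and carbonic, as in carbonic anhydrase, which supplies bicarbonate for shell mineral, at least 3.98-fold higher (adjusted p = 0.0189). Caveolin, a scaffold of membrane pits, was at least 34-fold higher (adjusted p = 0.00777), being well above background on 3 of 3 pediveliger arrays and on 0 of 3 veliger arrays. Of 215 cilia probes 2 rose, of 2 transcripts, dynein by 1.37 ± 0.22 (adjusted p = 0.0166) and tctex1 by 1.35 ± 0.22 (adjusted p = 0.0185). The cilia list had a median of -0.056 and was not called (camera's adjusted p = 0.465), with 0.15 under median centring, which moved the median of all probes by 0.20, and 0.22 within slide 2 (adjusted p = 0.925 with an estimated correlation), where 1 pediveliger stands against 3 veligers. At the preset correlation it was negative and called without veliger 1 (-0.11, adjusted p = 0.0495) or pediveliger 1 (-0.18, adjusted p = 0.00261), and positive and not called without veliger 2 (0.014) or pediveliger 2 (0.046). Lists with 1 array left out were not tested with an estimated correlation, here or elsewhere.

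Further rises were cdc42, a small GTPase of cell polarity, by 4.33 ± 0.88 (adjusted p = 0.0493) and ctrl_halru, a chymotrypsin-like protease, by 3.84 ± 0.72 (adjusted p = 0.0406). Rises were also measured for the probes named very, by 3.54 ± 0.69 (adjusted p = 0.0415), macrophage, by 3.52 ± 0.55 (adjusted p = 0.0166), hydrogenase, by 2.41 ± 0.45 (adjusted p = 0.0406; the other probe of its transcript -0.13) and rapunzel, by 1.99 ± 0.36 (adjusted p = 0.0353). Glutathione, an antioxidant name, was at least 2.03-fold higher (adjusted p = 0.0415). Named falls were oxidized at -1.80 ± 0.35 (adjusted p = 0.0415), proprotein, at least 2.66-fold lower (adjusted p = 0.0225), and myosin, the motor of muscle, at -0.81 ± 0.14 (adjusted p = 0.025; the other probe of its transcript 0.13).

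As lists, foot and byssus had a median of 2.27 with 26 of 26 probes positive (0 past the threshold over all probes, 17 higher adjusted over the list alone; camera's adjusted p = 3.41e-14, and adjusted p = 0.829 with an estimated correlation). Its proximal thread protein was at 3.90 ± 0.83 (adjusted p = 0.0596), precollagen at 3.19 ± 0.82 (adjusted p = 0.0696) and foot at least 2.29-fold higher (adjusted p = 0.0707). Shell formation had 0.43 (3 higher, 26 adjusted over the list alone; adjusted p = 7.79e-10, and adjusted p = 0.829 with an estimated correlation). Immune effectors had 0.38 (4 higher; 59 higher and 4 lower adjusted over the list alone; adjusted p = 2.8e-10, and adjusted p = 0.829 with an estimated correlation) and digestive enzymes had 0.60 (adjusted p = 1.03e-06, and adjusted p = 0.829 with an estimated correlation). Just short of the threshold were Apolipophorins, lipid carriers, at 4.43 ± 0.93 (adjusted p = 0.0564), low-density at 3.87 ± 0.84, dopamine at 1.79 ± 0.40 (adjusted p = 0.061 for both; the other probe of the dopamine transcript 0.66) and fatty at -0.77 ± 0.19 (adjusted p = 0.0677).

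**Figure D3:**
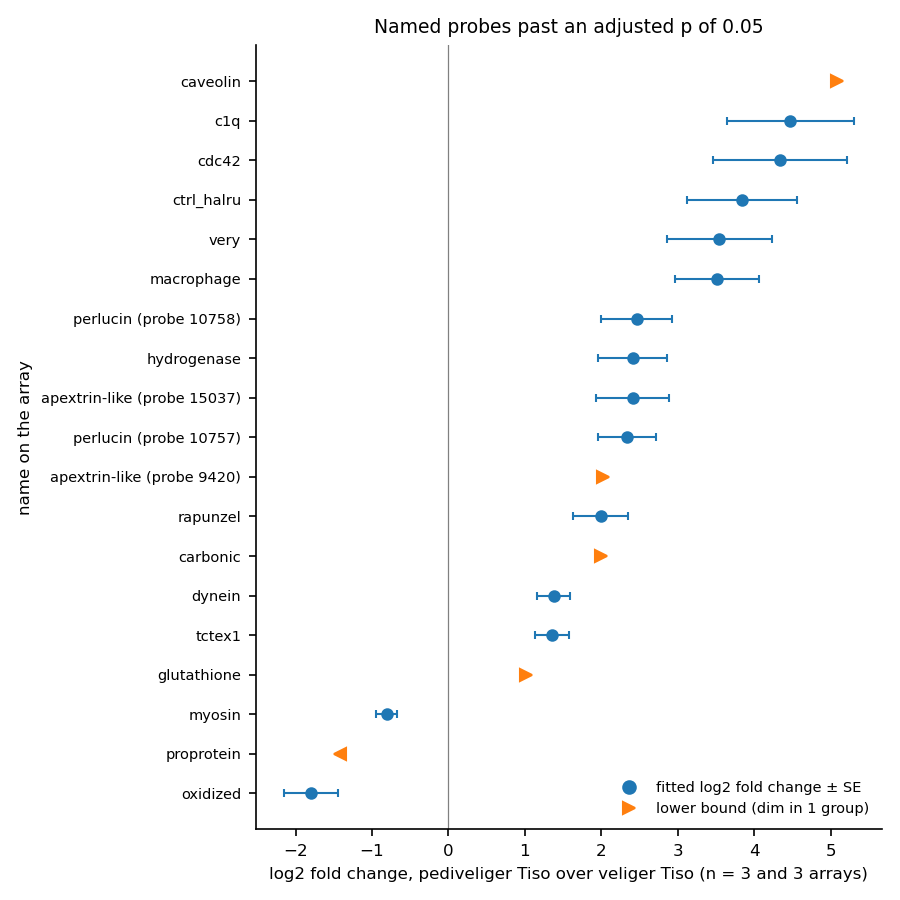
Log2 fold change of Tiso pediveligers over Tiso veligers (3 arrays each) for the named probes past an adjusted p of 0.05. Circles are fitted values with their SE, and triangles are lower bounds on the size for probes not well above background in 1 group, caveolin having the largest at 34-fold.

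The 87 called probes belong to 74 transcripts, and 37 are named. All 87 had non-overlapping replicates, as did 19.1% of all probes, where chance gives 10% if arrays are interchangeable. A small p favours such probes, so this is no separate support for the calls. COC juveniles against COC pediveligers had 28.7% of all probes not overlapping, with 0 called. The deposited quantile table called 96 higher and 6 lower, and the Cy5 channel alone 56 higher and 0 lower. Within slide 2 (1 pediveliger, 3 veligers, as with the slide as a block) 5 other probes of 5 transcripts were called, 3 higher and 2 lower, with 0 of the 87 among them. The medians there, which rest on that 1 pediveliger, were 2.42 for foot and byssus (adjusted p = 8.55e-12, and adjusted p = 0.925 with an estimated correlation), 0.088 for shell formation, 0.026 for immune effectors and 0.081 for digestive enzymes. The count was 25, 1205 or 12 without Tiso veliger 1, 2 or 3 and 2031, 0 or 11 without Tiso pediveliger 1, 2 or 3. Without veliger 2 the list medians were 1.45 for foot and byssus, 0.67 for shell formation, 0.71 for immune effectors and 1.09 for digestive enzymes. Without veliger 3 immune effectors had 0.20 and digestive enzymes 0.21, which ended the call of the latter (adjusted p = 0.0747). Without pediveliger 1 shell formation had 0.66 and immune effectors 0.59, and without pediveliger 2 they had 0.26 and 0.21, and digestive enzymes 0.35.

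Between Tiso pediveligers and Tiso juveniles limma called 0 probes, with 931 at an unadjusted p under 0.05, and the smallest adjusted p was 1. The 931 are under the share of 0.05 of the 39403 tested probes that is expected where nothing changes. The foot and byssus list had a median log2 change of -0.53 with 26 of 26 probes negative (camera's adjusted p = 0.000358, and adjusted p = 0.63 with an estimated correlation; -0.60 within slide 3, as with the slide as a block). Shell formation had -0.17 (adjusted p = 3.75e-05, and adjusted p = 0.63 with an estimated correlation; -0.40 within slide 3), with perlucin at -1.32 ± 0.43 (SE, n = 2 juveniles and 3 pediveligers). Muscle had 0.18 (adjusted p = 0.000568, and adjusted p = 0.63 with an estimated correlation; 0.24 within slide 3, and -0.31 in the Cy5 channel alone), with myosin at 0.57 ± 0.16. Further values were -1.29 ± 0.33 for c1q, 4.24 ± 1.36 for pedal and 1.06 ± 0.32 for phytanoyl-, a name from phytanoyl-CoA enzymes of fatty acid oxidation. Others were -0.75 ± 0.25 for tctex1 and -0.55 ± 0.21 for a ribosomal probe. The last 2 changed sign with other scaling (tctex1 2.75 in Cy5 alone and 2.59 in the quantile table, ribosomal 0.18 with median centring and 0.63 in the quantile table). Tiso juvenile 1 had almost no signal, which pulls the juvenile mean towards 0, and without it 5 probes were called. The shell formation median was -0.088 or -0.29 without juvenile 1 or 2, -0.40 without pediveliger 1, and 0.007 without pediveliger 2, where it was not called (adjusted p = 0.106). That of muscle was 0.11 without juvenile 2.

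The diets were compared at each stage, with positive values higher on Tiso. In veligers ribosomal proteins had a median log2 difference of 0.58 (306 of 324 positive; 2 higher adjusted over the list alone; camera's adjusted p = 7.73e-23, and adjusted p = 0.245 with an estimated correlation), with 1 probe at 0.83 ± 0.18 (SE, n = 3 and 3). Digestive enzymes had 0.87 (130 of 159 positive; adjusted p = 5.97e-15, and adjusted p = 0.554 with an estimated correlation), with beta-glucan at 2.13 ± 0.60. Immune effectors had 0.36 (2 higher adjusted over the list alone; adjusted p = 7.38e-13, and adjusted p = 0.554 with an estimated correlation), with c1q at 1.34 ± 0.23 (limma adjusted p = 0.395). The lipid lists, closest to the dietary question, had 0.12 for fatty acid metabolism (115 of 166 positive; adjusted p = 0.00773, and adjusted p = 0.554 with an estimated correlation) and 0.27 for lipid transport and storage (76 of 108 positive; adjusted p = 9.08e-05, and adjusted p = 0.554 with an estimated correlation). Fatty was at 1.81 ± 0.54 and low-density, as in lipoproteins, at 1.95 ± 0.57, with proteasome at 1.03 ± 0.26 and caspase, a protease of apoptosis, at 0.68 ± 0.16, none past the threshold (adjusted p from 0.574 to 0.576). Limma called 0 probes, with 2631 at an unadjusted p under 0.05. Within slide 2 (3 Tiso arrays, 1 COC array, as with the slide as a block) 0 were called, with 2448 at an unadjusted p under 0.05. The medians there were 0.15 for ribosomal proteins, 0.60 for digestive enzymes, 0.44 for immune effectors, 0.16 for fatty acid metabolism and 0.20 for lipid transport. Without Tiso veliger 2 the calls ended for digestive enzymes (0.28, adjusted p = 0.164), immune effectors (0.13, adjusted p = 0.208), fatty acid metabolism (0.020, adjusted p = 0.714) and lipid transport (0.10, adjusted p = 0.308). Without COC veliger 1 the medians were 0.30 for ribosomal proteins, 0.45 for digestive enzymes and 0.24 for immune effectors. Ribosomal proteins had 0.23 without Tiso veliger 1, and immune effectors 0.54 without COC veliger 2 and 0.55 without Tiso veliger 3. Without COC veliger 3 the count was 112, and fatty acid metabolism was not called (0.12, adjusted p = 0.0774).

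In pediveligers shell formation had a median of 0.45 on Tiso over COC (105 of 132 positive; camera's adjusted p = 1.72e-10, and adjusted p = 0.439 with an estimated correlation), with perlucin at 1.36 ± 0.39 (SE, n = 3 and 3). Immune effectors had 0.40 (474 of 567 positive; adjusted p = 8.7e-13, and adjusted p = 0.439 with an estimated correlation), with c1q at 4.15 ± 0.83. Cilia had -0.25 (163 of 215 negative; adjusted p = 5.88e-07, and adjusted p = 0.439 with an estimated correlation), although dynein itself was at 0.79 ± 0.22. Under median centring, which moved the median of all probes by 0.14, cilia had 0.004 and lipid transport and storage 0.069. Fatty acid metabolism (0.069, adjusted p = 0.198) and lipid transport and storage (-0.13, adjusted p = 0.0504) were not called, with fatty at 0.48 ± 0.16 and Apolipophorins at 2.99 ± 0.93 (the other probes of these transcripts 0.20 and 1.16). At the preset correlation lipid transport was called without COC pediveliger 2 (-0.22, adjusted p = 0.000577), Tiso pediveliger 1 (-0.15, adjusted p = 0.0196) or Tiso pediveliger 2 (-0.12, adjusted p = 0.0368). It was also called from the processed signals (-0.29, adjusted p = 0.0135), the series matrix (-0.29, adjusted p = 0.0182) and the quantile table (-0.10, adjusted p = 0.0337), whereas an estimated correlation gave an adjusted p = 0.535. Its median was -0.063 or -0.035 without COC pediveliger 1 or 3 and -0.080 without Tiso pediveliger 3. Fatty acid metabolism was called without COC pediveliger 1 (0.10, adjusted p = 0.0482) and had 0.12 without Tiso pediveliger 1, 0.015 without COC pediveliger 2 and 0.021 without Tiso pediveliger 2. Further values were 1.69 ± 0.41 for dopamine, 1.66 ± 0.43 for cathepsin, 0.88 ± 0.22 for glutathione and -0.57 ± 0.14 for myosin (the other probe -0.23), each with a limma adjusted p of 0.433. At this stage limma called 0 probes, with 3761 at an unadjusted p under 0.05. Within slide 2 (1 Tiso array, 3 COC arrays, as with the slide as a block) 3 probes of 3 transcripts were called, 2 higher and 1 lower. The medians there were 0.088 for shell formation, 0.026 for immune effectors, 0.067 for cilia and -0.031 for fatty acid metabolism, the last 2 reversed, and -0.062 for lipid transport. Without Tiso pediveliger 1 the count was 1314, and without COC pediveliger 1 it was 19. Without COC pediveliger 2 the medians were 0.26 for shell formation and 0.23 for immune effectors, and without Tiso pediveliger 2 they were 0.28 and 0.22, with -0.12 for cilia.

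In juveniles muscle genes had a median of 0.39 on Tiso over COC (111 of 137 positive; camera's adjusted p = 3.7e-07, and adjusted p = 0.646 with an estimated correlation) and cilia 0.17 (151 of 215 positive; adjusted p = 0.000227, and adjusted p = 0.962 with an estimated correlation). Both were negative in the Cy5 channel alone (-0.30 and -0.20), which moved the median of all probes by -0.22, and cilia also under median centring (-0.016), which moved it by -0.15. Lipid transport and storage had 0.055 (adjusted p = 0.275), and was negative in Cy5 alone (-0.29), under median centring (-0.051) and in the quantile table (-0.027). It was called without COC juvenile 2 (0.10, adjusted p = 0.0242) and negative without COC juvenile 3 (-0.034), with 0.097 and 0.089 without COC juvenile 1 and Tiso juvenile 1. Fatty acid metabolism had -0.048 (adjusted p = 0.809), with -0.016 without COC juvenile 2 and -0.012 without Tiso juvenile 2. Cathepsin was at 2.88 ± 0.89 (SE, n = 2 and 3), axonemal at 1.28 ± 0.44 (the other probe of its transcript 0.50), tctex1 at -0.68 ± 0.25 (2.83 in Cy5 alone and 2.73 in the quantile table) and a ribosomal probe at -0.80 ± 0.24 (0.088 from the processed signals and 0.055 from the series matrix). Limma called 0 probes, with 589 at an unadjusted p under 0.05, which is under the share of 0.05 of the 39403 tested probes expected where nothing changes. All 5 arrays lay on slide 3, where 0 were called (1000 unadjusted) and the medians were those given. Without Tiso juvenile 1, the array with almost no signal, 5 probes were called. Its ratios lie near 0, so the Tiso values here average Tiso juvenile 2 with an almost blank array. COC juveniles had list medians of -0.285 ± 0.165 for muscle and -0.116 ± 0.012 for cilia (SD, n = 3). Ratios near 0 therefore give a positive difference by themselves. With 1 array left out the differences ranged from 0.286 to 0.471 for muscle and from 0.147 to 0.176 for cilia.

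Averaged over the 3 stages, digestive enzymes had a median of 0.54 on Tiso over COC (134 of 159 positive; camera's adjusted p = 7.43e-26, and adjusted p = 0.317 with an estimated correlation; 0.28 with the slide as a block). Immune effectors had 0.24 (486 of 567 positive; adjusted p = 1.75e-19; 0.12 with the block), shell formation 0.22 (adjusted p = 1.34e-11; 0.11 with the block), the proteasome 0.21 (adjusted p = 7.25e-12; 0.21 with the block), antioxidant enzymes 0.14 (adjusted p = 7.95e-08; 0.13 with the block) and chaperones 0.099 (adjusted p = 0.000143; 0.066 with the block). Each of these 5 had an adjusted p = 0.317 with an estimated correlation. Fatty acid metabolism had 0.064 (114 of 166 positive; adjusted p = 0.00939, and adjusted p = 0.429 with an estimated correlation; 0.046 with the block), lipid transport and storage 0.074 (adjusted p = 0.0251, and adjusted p = 0.546 with an estimated correlation; 0.085 with the block) and apoptosis 0.068 (adjusted p = 0.0127, and adjusted p = 0.468 with an estimated correlation; 0.025 with the block). Lipid mediator enzymes had 0.012 (adjusted p = 0.898; 0.081 with the block; -0.015 to 0.030 with 1 array left out), with a negative median under median centring (-0.067), in the quantile table (-0.046) and in Cy5 alone (-0.039). In Cy5 alone, which moved the median of all probes by -0.066, the proteasome (-0.028), chaperones (-0.030), fatty acid metabolism (-0.022), lipid transport (-0.027) and apoptosis (-0.008) were negative too. Without Tiso veliger 2 the medians were 0.15 for immune effectors, 0.053 for chaperones, 0.046 for fatty acid metabolism (adjusted p = 0.358) and 0.035 for lipid transport (adjusted p = 0.516), and the calls of the last 2 ended. Chaperones had 0.063 without COC veliger 3. The call of fatty acid metabolism also ended without COC pediveliger 2 (0.041, adjusted p = 0.093). That of lipid transport ended without COC veliger 1 (0.043, adjusted p = 0.218), COC pediveliger 2 (0.047, adjusted p = 0.251), COC juvenile 3 (0.026, adjusted p = 0.365) or Tiso pediveliger 1 (0.033, adjusted p = 0.37), and that of apoptosis without COC veliger 2 (0.054, adjusted p = 0.0784) or Tiso pediveliger 3 (0.063, adjusted p = 0.0642).

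Single genes higher on Tiso at each stage included caspase at 0.40 ± 0.10 (SE, 8 Tiso and 9 COC arrays; the other probe of its transcript 0.18), perlucin at 0.90 ± 0.28, cathepsin at 0.78 ± 0.26, nadh at 0.57 ± 0.21, fatty at 0.55 ± 0.22, a ribosomal probe at 0.50 ± 0.14 and prostaglandin, a lipid mediator name, at 0.21 ± 0.09. Others were lower on Tiso at each stage. Among them were phytanoyl- at -0.30 ± 0.10, which had the smallest p of the fatty acid metabolism list, and engrailed at -0.30 ± 0.11. Further ones were a dopamine probe at -0.28 ± 0.12, a cyclin-dependent probe at -0.24 ± 0.16 and one named prostag at -0.22 ± 0.17 (the other probe -0.073). Other probes named dopamine went the other way. They were at 1.25 ± 0.51 and 0.76 ± 0.31, both higher on Tiso at each stage, and at 1.47 ± 0.46 without the same sign at each stage. A c1q probe at 0.58 ± 0.16 did not keep its sign at each stage. The 8 Tiso arrays include Tiso juvenile 1, which had almost no signal and ratios near 0. In juveniles the sign therefore rests on the other Tiso juvenile averaged with an almost blank array. Ratios near 0 by themselves give a juvenile difference opposite in sign to the COC juvenile mean. The same sign at each stage is thus weaker evidence in juveniles. Cathepsin (-0.36), fatty (-0.12) and ribosomal (-0.51) were negative in the Cy5 channel alone. In the mean limma called 0 probes, with 997 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and 0 with the slide as a block. The 997 are under the share of 0.05 of the 39403 tested probes that is expected where nothing changes. Without Tiso juvenile 1 the count was 1.

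Whether the diet difference itself differed between stages was tested directly. The named probes with the smallest p, of which 3 were chosen after their values were seen, included calmodulin, a calcium sensor, with Tiso over COC log2 differences of 0.80 in veligers, -0.54 in pediveligers and -0.27 in juveniles, and strombine, a name from an anaerobic enzyme of molluscs, with 1.18, 0.084 and -0.30 (0.80, 0.21 and -0.16 on the other probe of its transcript). Caveolin had 2.87 in pediveligers and -1.04 in juveniles, and in veligers it was well above background on 0 of 3 arrays of each diet, so no difference is given there. None passed the threshold (F-test, adjusted p = 0.679 for each). Limma called 0 probes, with 2811 at an unadjusted p under 0.05, and 0 of each of the 20 lists' members were called. The pairwise differences of the diet contrasts also called 0, with 2462, 2135 and 3903 at an unadjusted p under 0.05 for pediveliger minus veliger, juvenile minus veliger and juvenile minus pediveliger. With the slide as a block 0 were called, and without COC pediveliger 1 or Tiso juvenile 1 the count was 15 or 3.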

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

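The tests of the slide and of a wrong label for the array profiles, and the tests of the eggs, the dim arrays and the slide for the stage result, were chosen after the results were seen. Among spots outside the comparisons, 1400 spots of 140 titration probes carried signal: on the median array 7.43% of them were well above background in Cy5 and 11.1% in Cy3, against 0.325% of negative control spots in Cy5 and 58.6% of probe spots. This signal lies above the level of the control spots, and no explanation of it was tested.

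Array profiles often lay closest to an array of another label, as for 14 of 22 arrays. Pairs of different stages on 1 slide correlated more than pairs of 1 stage on different slides (mean r 0.272 over 45 pairs and 0.0932 over 16, a difference of 0.179; permutation p = 1e-05, the smallest the permutations can give), so the slide may contribute. Slides were shuffled freely over the 22 arrays, although each slide held neighbouring stages, so this p does not part the slide from age or diet. Pairs of arrays that differed more in their share of Cy5 spots above background correlated less (Spearman's rho -0.212, permutation p = 0.0086; Pearson's r -0.269, permutation p = 0.002; rho -0.176 without the 2 arrays farthest from the median; 231 pairs of 22 arrays), so weak signal may contribute as well. The array labelled trochophore 2 had a foot and byssus median of 0.204, within the range of the COC pediveligers (-0.212 to 0.842) and above the highest egg (-0.628). A wrong label would give this, but it rests on 1 list. The highest COC veliger (-0.185) and the Tiso juveniles (-0.003 and 0.108), 1 of them the array with almost no signal, also lay in that range. The value therefore does not single out a pediveliger. The list's foot probes CUST_8103_PI427809864 and CUST_9938_PI427809864 were well above background on 0 of 3 trochophore arrays, and CUST_16581_PI427809864 and CUST_1634_PI427809864 on 1 of 3. The labels of egg 1 and trochophore 1 were not tested. Trochophore 1 correlated with eggs 2 and 3 at 0.702 and 0.834, and egg 1 with them at 0.271 and 0.345. None of these tests argues against its explanation, the close pairs across slides (trochophore 2 with COC pediveliger 2, trochophore 3 with Tiso veliger 2) are not accounted for by a shared slide, and differences between cultures of a stage remain untested.

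The 87 probes called between Tiso veligers and Tiso pediveligers could reflect the slide, since all 3 veligers lay on slide 2 and pediveligers 2 and 3 on slide 3. Of the 87 probes with the largest moderated t between those 2 pediveligers and 1 veliger, 85.1%, 70.1% or 73.6%, depending on the veliger used, kept their sign between pediveliger 1 and the other veligers, all on slide 2. Their median change in that direction was 0.49, 0.25 or 0.32 there, against 1.65, 2.29 or 1.78 across slides, although choosing the largest values also makes a second measurement smaller. The lowest share was 70.1%. It lies between 60%, set beforehand as the most that a slide effect allows, and 75%, above which a slide effect would be argued against. Slide and stage therefore cannot be told apart for these sets of probes, each chosen anew with its veliger. The 87 called probes themselves were not tested in this way, so for them slide and a difference between the stages both stay open. The 10 splits of these 6 arrays are too few for a share under 0.05, with 87 called by the labels and at most 70 by another split (pediveliger 1 with veligers 1 and 3).

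The 185 probes called over the stages could depend on the eggs alone, on weak signal or on the slide. Without eggs or juveniles 0 were called, with 167 and 184 of the 185 at an unadjusted p under 0.05, whereas without trochophores, COC veligers or COC pediveligers 928, 121 and 370 were called, 185, 91 and 183 of the 185 among them, so 1 group less does not by itself end the calls and the part of the eggs cannot be told apart from that of the juveniles. Without the 4 dimmest arrays 4022 were called, with 169 of the 185 (91.4%) among them, but this leaves 1 egg and 2 trochophore arrays, so weak signal cannot be told apart from stage. With the slide as a block 0 were still called, and eggs lay only on slide 1 and COC juveniles only on slide 3, so slide and stage cannot be told apart either. Of 100 drawn regroupings, the real one included, 2 gave as many calls (185 by the labels, 475 at most otherwise), so chance is excluded at 0.05 only for groupings drawn without regard to the slide, and not for groupings that follow it.

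For the remaining comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Trochophores against eggs gave 1 call by the labels and 4639 at most by another split, with egg 1 and trochophores 2 and 3 on 1 side. All 6 lay on slide 1, so this split does not follow the slide. Eggs 2 and 3 and trochophore 1, on the other side, correlated with one another at 0.702 to 0.848, and the cause was not tested. COC pediveligers against COC veligers gave 0 and at most 1159 (pediveligers 1 and 3 with veliger 1), a split with slide 2 on both sides. Those 3 arrays had 50.7% to 74.9% of spots well above background in Cy5 and the other side 33.7% to 47.3%. Signal strength and a structure of the samples therefore cannot be told apart for this split. The diets in veligers gave 0 and at most 3714, with COC veligers 1 and 2 and Tiso veliger 2 on 1 side. That split largely follows the slide, since the other side lay on slide 2 and those COC veligers were the 2 arrays on slide 1. Within slide 2 only 1 COC array is left, so a count of calls there does not bear on this. COC veligers against trochophores gave 0 and at most 2, COC juveniles against pediveligers 0 and 0, and the diets in pediveligers 0 and at most 25 (COC pediveliger 1 with Tiso pediveligers 2 and 3). For the mean diet difference and for its differences between stages the labels gave 0 calls, which all 100 drawn regroupings reach by construction (at most 6 and 0 calls), so they say nothing about chance.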

How the results depend on the processing

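The settings without the array with almost no signal, without the 4 dim arrays and with means per transcript, the lists as first written, the slide block with an estimated correlation and the within-slide values were chosen after the data were seen. Unless stated, the cause of a change was not tested. Aquantile scaling leaves log ratios as they are, so its values were fixed by construction and are left out here. Of 305 other recomputed counts of called probes 179 were 0 in both settings, and of the remaining 126 only 13 stayed within 1.5 times the value reported. A 2-fold minimum gave 179, 1 and 80 where 185, 1 and 87 were reported. Of 637 recomputed values of the 28 named genes past the threshold 283 fell short of it and 354 did not, and 0 reversed. For the genes of the stage F-test the value was the F statistic, which has no direction, so these could not reverse.

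Counts are given in the order in which the comparisons stand in the report. Over the stages 2075 probes were called from the processed signals, 8462 with median centring, 1149 in Cy5 alone, 4147 from the series matrix, 280 from the quantile table. The count was 115 without a probe filter, 0 with the stricter filter, 57 with 1 probe per name, 1 on the compared groups alone, 1 with trend and robust prior, 0 with the slide as a block. It was 65 without the failed array, 4022 without the 4 dim arrays and 70 with means per transcript. From egg to trochophore 952 were called from the processed signals, 96 in Cy5 alone, 1408 from the series matrix, 5087 without the dim arrays, and 0 with median centring, the quantile table, the stricter filter, 1 probe per name, the compared groups alone or trend and robust prior. From trochophore to COC veliger the slide block gave 101, and from COC veliger to pediveliger the stricter filter 2. From COC pediveliger to juvenile the series matrix gave 11 and the compared groups alone 2. From Tiso veliger to pediveliger 150 were called from the processed signals, 23 with median centring, 56 in Cy5 alone, 426 from the series matrix. It was 43 without a filter, 1 with the stricter filter, 2 with 1 probe per name, 13 on the compared groups alone, 5 with the slide block, 34 without the failed array and 14 without the dim arrays. From Tiso pediveliger to juvenile Cy5 alone gave 26, 5 came from the quantile table, and leaving out the failed or the dim arrays 5 and 3.

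Between the diets in veligers the processed signals and the series matrix gave 1 each. In pediveligers Cy5 alone gave 8, the stricter filter 1, the compared groups alone 2 and the slide block 3. In juveniles Cy5 alone gave 11, 6 came from the quantile table, and leaving out the failed or the dim arrays 5 and 3. For the mean over stages the quantile table and leaving out the failed or the dim arrays gave 1 each, and for the differences between stages Cy5 alone gave 15, 1 came from the quantile table and 3 and 1 from those omissions. Array weights called 33177, 8778, 4432, 9428, 2775, 15064, 9943, 11713, 10759, 2366, 2780 and 20598 over the 12 comparisons. Their iterative estimate stopped before its tolerance and ranged from 0.138 for COC veliger 1 to 46.8 for egg 3, so these counts rest on few arrays. The stricter filter left only 6 probes, which sets its counts by construction.

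Leaving out 1 array at a time gave 1 to 5055 probes over the stages, 0 to 3524 from egg to trochophore, 0 to 979 to COC veliger, 0 to 881 to COC pediveliger, 0 to 22 to COC juvenile, 0 to 2031 from Tiso veliger to pediveliger and 0 to 5 to Tiso juvenile. It gave 0 to 112, 0 to 1314 and 0 to 5 between diets in veligers, pediveligers and juveniles, 0 to 1 for their mean and 0 to 15 for the differences between stages. With 1 Tiso juvenile left, that array is assumed to vary like the other groups. The replicate block gave 15 over the stages and 14 from Tiso veliger to pediveliger, and moved no other count by over 1.5 times. Its numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.0612 on average (18 of 70 pairs over 0.1) and those of other numbers at 0.03. The scan sessions are the same as the slides and were not run apart from them.

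Median centring shifted the median log2 change of all probes by 0.33 from egg to trochophore, 0.45 from COC pediveliger to juvenile, 0.20 from Tiso veliger to pediveliger, 0.14 between diets in pediveligers and -0.15 in juveniles. The series matrix shifted it by 0.42, 0.20 and, from Tiso pediveliger to juvenile, 0.10, and Cy5 alone by -0.20 there and -0.22 between diets in juveniles. In Cy5 alone these reversed: cyp-like (0.16) and nadh (0.066) from egg to trochophore, tctex1 to Tiso juvenile (2.75) and between diets in juveniles (2.83), cathepsin (-0.36), ribosomal (-0.51) and fatty (-0.12) in the mean over stages. So did the lists muscle to Tiso juvenile (-0.31) and muscle (-0.30), cilia (-0.20) and lipid transport (-0.29) between diets in juveniles. In the quantile table tctex1 (2.59 and 2.73, the same comparisons), ribosomal to Tiso juvenile (0.63) and lipid mediator enzymes in the mean (-0.046) reversed. Median centring reversed ribosomal to Tiso juvenile (0.18) and lipid mediator enzymes (-0.067), and the processed signals (0.088) and the series matrix (0.055) ribosomal between diets in juveniles. The slide block reversed oxidative phosphorylation to COC veliger (0.044), cilia (0.19) and immune effectors (-0.26) to COC juvenile, cilia (0.22) from Tiso veliger to pediveliger, and cilia (0.067) and fatty acid metabolism (-0.031) between diets in pediveligers. Median centring also turned the list medians of egg envelope and germ line from egg to trochophore (0.30; series matrix 0.074), cilia (0.46), muscle (0.56) and ribosomal proteins (0.65) to COC juvenile, cilia from Tiso veliger to pediveliger (0.15), cilia (0.004) and lipid transport (0.069) between diets in pediveligers, and cilia (-0.016) and lipid transport (-0.051; quantile table -0.027) in juveniles. Cy5 alone, which shifted all probes by -0.066 in the mean over stages, turned there the proteasome (-0.028), fatty acid metabolism (-0.022), lipid transport (-0.027), chaperones (-0.030), apoptosis (-0.008) and lipid mediator enzymes (-0.039). Leaving out 1 array, medians ranged from -0.006 to 0.58 for ribosomal proteins to trochophore, -0.58 to 0.044 for oxidative phosphorylation to COC veliger, -0.18 to 0.046 for cilia from Tiso veliger to pediveliger, -0.40 to 0.007 for shell formation to Tiso juvenile, -0.034 to 0.10 for lipid transport between diets in juveniles and -0.015 to 0.030 for lipid mediator enzymes in the mean. Of the 53 list results, 165 of 729 values recomputed under other settings lost their call with the sign kept, 5 gained one (lipid transport between diets in pediveligers, also with the replicate block, adjusted p = 0.0476, and without the dim arrays, adjusted p = 0.044) and 35 changed sign, and of 421 with 1 array left out these were 21, 7 and 11. The 16 lists of at least 5 members as first written were called 9, 8, 6, 6, 4, 6, 5, 7, 4 and 7 times over the 10 comparisons and 0 times with an estimated correlation. Signal over background limits eggs 1 and 3, trochophore 1 and Tiso juvenile 1, where under 25% of spots exceeded it.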

Other observations

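The levels in this part were chosen after the results were seen, and they are given without a test. Cell cycle genes had a list median of 0.59 ± 0.61 in eggs (SD, n = 3 arrays; range -0.056 to 1.17) and means between -0.049 and 0.073 in the other 7 groups. Probes named for algal proteins had means of -0.05 ± 0.14 in eggs and -0.09 ± 0.19 in trochophores, the groups without a diet. In fed groups they had -0.64 ± 0.68 in COC veligers, -0.27 ± 0.11 in Tiso veligers, 0.05 ± 0.24 in COC pediveligers, -0.17 ± 0.14 in Tiso pediveligers, -0.13 ± 0.15 in COC juveniles and 0.10 ± 0.16 in Tiso juveniles (n = 2). The COC veligers were the most variable of these groups, at -1.42 to -0.19 on single arrays. Egg envelope and germ line genes ranged over the groups only from -0.12 ± 0.02 in COC veligers to 0.07 ± 0.06 in COC juveniles.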
